A study of Mus musculus with 37 samples.

How the data were processed

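RNA was sequenced from mature luminal cells that had been sorted by flow cytometry from mammary glands of mice, with libraries made from cDNA by the Nextera XT method. Per the labels, the mice were raised to an age of 8 weeks, ovariectomized and given pellets for 8 days that held placebo, E2 or P4, and a further treatment combined E2 and P4. The labels name 3 genotypes of Esr1, which encodes estrogen receptor alpha: WT, D542G and Y541S. The 37 libraries fell into 12 groups, each genotype with each of 4 treatments, with 3 libraries in 11 groups and 4 in WT P4. The group and number of every library were taken from its title. The series' design text calls the samples biological replicates, and no label says whether each came from a separate animal or from a pool, so p-values measure the spread between these samples.

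The authors deposited a table per library with the counts per gene and the RPKM that they derived from them. The deposited counts were whole numbers for 52636 genes named by Ensembl identifier. The submitters' processing notes name the build GRCm38; the aligner, the counting tool and the use of strand were not given in the sources used here. The width per gene in the deposited tables equalled the genomic span of the gene, introns included, for 85.6% of genes in GENCODE M21 of GRCm38, and was within 5% of it for 94.4%. Symbols were matched by identifier for 52489 genes, and the other 147 held at most 0.007% of the counts of any library. The authors' RPKM used a total per library of which the gene counts made up 87.97% to 90.2%; RPKM served for no test. Of 1347 protein-coding genes whose span lay wholly within that of other genes, 1153 (85.6%) had a count of 0 in all libraries, against 2314 of 11842 (19.5%) with no overlap. A count of 0 for such a gene was therefore not read as absence of its RNA. Csn3, Tspan8, Slc7a5, Tk1, Gins2, Cdt1, Mvd, Lipe, Ms4a1, Alas2, Fgf7, Muc15 and H2-Oa were list members of this kind at 0, and Tff1 was at 0 with 42.8% of its span overlapped.

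Total counts ran from 25.69 to 52.24 M per library, with a median of 41.26 M. The sample identifiers of 3 libraries (Y541S placebo 5, WT P4 4 and WT P4 5) belonged to a later number series; they had at most 31.33 M counts, and the other 34 at least 32.67 M. No pair of libraries of a group agreed within sampling noise: chi-square per degree of freedom over genes was 25.1 to 341.7 over 39 pairs.

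The main test was edgeR 4.0.16 under R 4.3.3 on the deposited counts of all 37 libraries, with a coefficient per group, filterByExpr by group, TMM factors (0.77 to 1.17), robust glmQLFit and glmQLFTest. It tested 18426 genes, with a common biological coefficient of variation of 0.458 and 25 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, over all genes within a comparison. The 20 comparisons set each hormone group against the placebo group of its genotype, WT E2+P4 against WT P4, the placebo groups against each other, each mutant's hormone response against that of WT cells as an interaction, and the E2+P4 response in WT cells against the sum of the single responses. Log2 fold changes are given ± SE, taken as the size of the log2 fold change over the square root of the F statistic. Levels are CPM, the counts scaled to the library's total over the tested genes times its TMM factor. They are given as mean ± SD over the libraries of a group. On simulated data with 100 changed genes of each size, the test recovered 34% of 2-fold and 89% of 4-fold changes in the WT E2 design, 39% and 91% in the WT P4 design, and 10% and 67% in the Y541S E2 interaction, with 7, 6 and 3 false calls.

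Fixed before the data were examined were the groups, comparisons, test, gene lists, the rule for naming genes and the alternatives, apart from the one said to be added. The 22 lists, with 367 genes, were estrogen receptor targets, progesterone receptor and steroid targets, paracrine factors of hormone-sensing cells, hormone-sensing luminal identity, luminal progenitor and alveolar markers, milk protein and lipid secretion genes, keratins and mucins of secretory epithelium, markers of basal and myoepithelial cells, fibroblasts, leukocytes, endothelium, adipocytes and erythroid cells, S phase, G2 and M phase, type I interferon response, immediate early and dissociation stress genes, unfolded protein response, cholesterol biosynthesis, glycolysis, antigen presentation by MHC class II, and mitochondrially encoded genes. Each was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated. Named were the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean log2 CPM of at least 2 and no overlap between the groups' libraries, a panel of 16 genes, up to 4 members with the smallest p of each list that passed camera, and the member with the highest CPM of each cell type list. The text names part of these, in that order, some are not reported here, and gene models without a symbol were counted and not named. By chance, 10% of genes would show no overlap between 3 and 3 libraries.

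The genes called higher and lower in WT E2+P4 against WT P4 were also tested by camera in the mutant placebo groups, since those comparisons share no library. Pearson correlations of fold changes across genes were set beside 20 simulations of unchanged groups that shared the control libraries. For genes with a group at 3 counts or fewer, the ratio of CPM was given with an exact 95% counting interval. The alternative was a bound from a floor of 3 counts over the group. For these ratios CPM was scaled to the total count over all genes, without TMM factors. Intervals and bounds cover counting error only, since the libraries carry no molecular identifiers.

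Alternatives were DESeq2 1.42.0 with its size factors, RLE factors in edgeR, no filter on low counts, the sample number as a block, removal of the 3 libraries of the later identifier series, removal of each library of the groups compared in turn, the estimated correlation, a list threshold of 0.01 and, for the correlations, genes with a mean log2 CPM of at least 2. Removal of WT placebo 2 and Y541S placebo 5 together was added after the data had been seen. Each comparison was also run on other splits of its libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The labels give neither pellet dose nor sequencing date, so neither was used here.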

Results

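Gene expression was measured by RNA sequencing in sorted mature luminal cells of mice with WT, D542G or Y541S Esr1, each given placebo, estradiol (E2), progesterone (P4) or both for 8 days after ovariectomy. Each of the 12 groups had 3 libraries, apart from WT P4 with 4. Deposited counts per library summed to 25.69 to 52.24 M, and 18756 to 20614 genes had at least 1 count. The 10 genes with most counts held 5.17% to 12.63% of a library. The 3 libraries with the fewest counts were those of the later identifier series. Levels are CPM as mean ± SD, with n = 3 unless stated, and differences are log2 fold changes ± SE. Positions are on GRCm38.

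Esr1, the targeted gene, encodes estrogen receptor alpha (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614). In WT cells it was at 688 ± 130 CPM in placebo, 24.3 ± 14.8 in E2, 537 ± 74.2 in P4 (n = 4) and 236 ± 106 in E2+P4. In D542G cells the levels were 171 ± 25.9, 87.6 ± 14.5, 105 ± 26 and 84.4 ± 18.6 CPM in the same order. In Y541S cells they were 82.1 ± 25.1, 66.8 ± 5.71, 76.4 ± 22.1 and 62.8 ± 5.63 CPM. Under placebo, Esr1 was lower than in WT cells in D542G (-2.01 ± 0.34 log2, adjusted p = 9.63e-04) and in Y541S (-3.07 ± 0.36 log2, adjusted p = 7.97e-07). Counts per gene do not show which allele was read, so the mutation itself was not seen here.

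**Figure D1:**
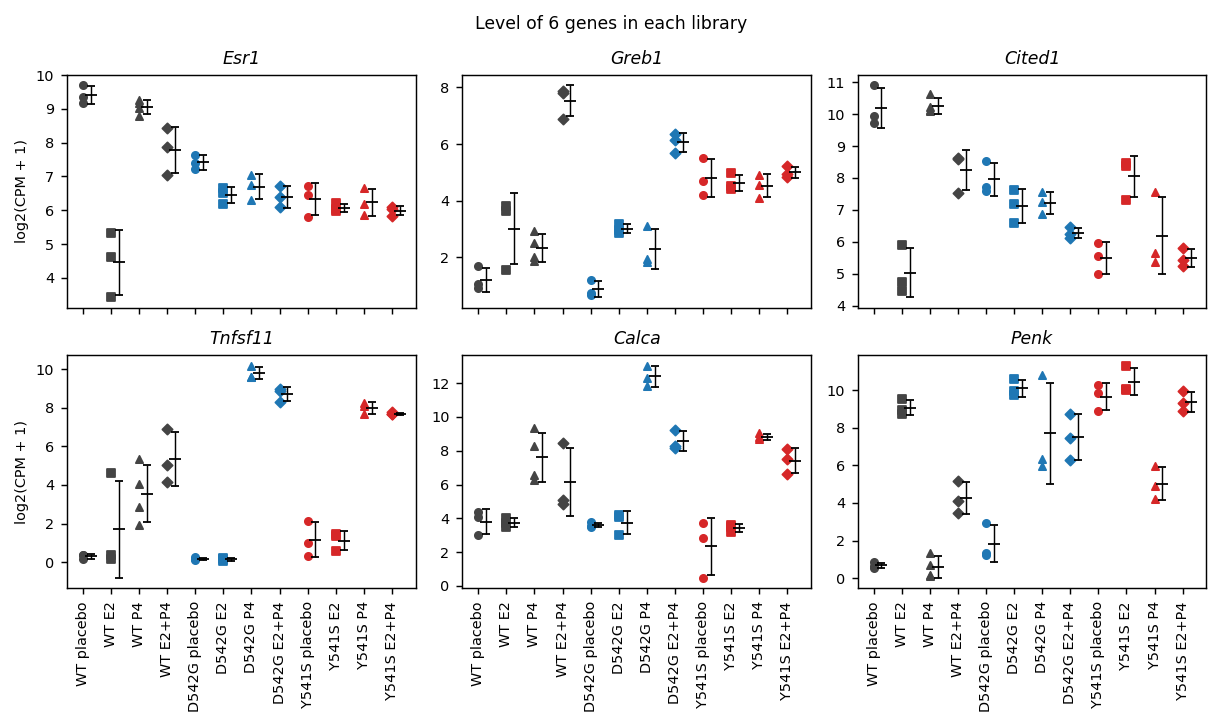
CPM of Esr1, Greb1, Cited1, Tnfsf11, Calca and Penk on a scale of log2(CPM + 1), by group; points are libraries and bars are group means ± SD. Esr1 was at 688 ± 130 CPM in WT placebo and at 24.3 ± 14.8 CPM in WT E2.

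Across all tested genes the first principal components held 19.8%, 11.4%, 8.9% and 6.9% of the variance. WT placebo libraries lay at -110.6, -79.7 and -109.1 on the first component. Y541S placebo 5 lay at 54.8, beside the Y541S E2 libraries at 63.6 to 73.1, whereas Y541S placebo 2 and 3 lay at -14.4 and -21.3. In Y541S placebo 5 the mean log2 CPM was 7.35 for progenitor and alveolar markers (5.79 and 5.2 in the other libraries of the group) and 8.03 for hormone-sensing markers (8.85 and 9.01). Its fibroblast markers were at 5.46 (4.09 and 3.99) and its leukocyte markers at 1.35 (-1.54 and 0.2). WT placebo 2 and WT P4 2 stood apart on the fourth component, at 68.3 and 60.4. Their G2 and M phase genes averaged 4.82 and 4.23 log2 CPM, against 0.68 and 1.16 in the other WT placebo libraries and 0.63 to 1.15 in the other WT P4 libraries. Basal markers averaged 4.37 in WT placebo 2 (1.7 and 1.92 in the others) and 3.97 in WT P4 2.

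**Figure D2:**
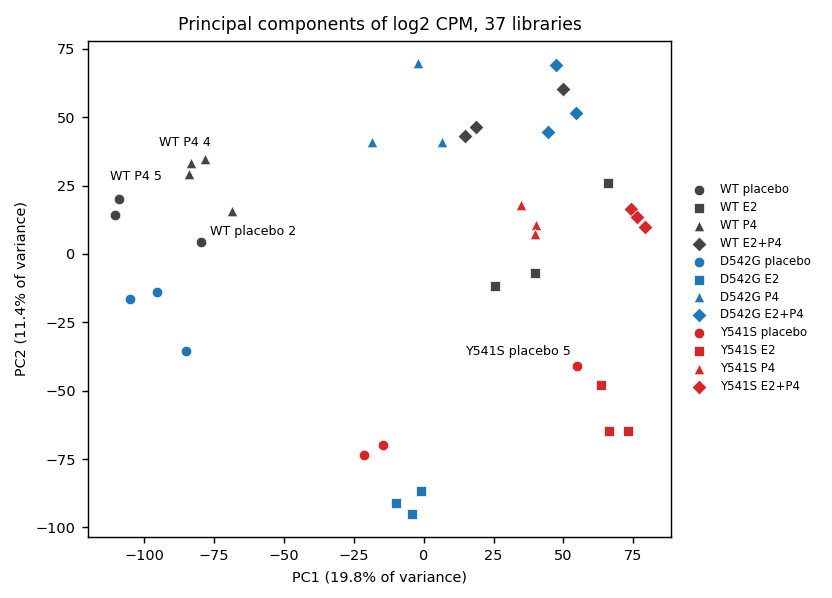
First and second principal components of log2 CPM over all tested genes, with each point a library and colour and shape for genotype and treatment. The axes hold 19.8% and 11.4% of the variance, and Y541S placebo 5 lies at 54.8 and -41.1.

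WT E2 against WT placebo asked which genes estrogen changes in cells with the intact receptor. Penk, which encodes preproenkephalin (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), rose from 0.614 ± 0.16 to 555 ± 168 CPM (9.82 ± 1.30 log2, adjusted p = 1.76e-06). Slpi, a secreted protease inhibitor, rose from 2.14 ± 0.615 to 816 ± 423 CPM. The chemokine gene Cxcl5 rose by 8.33 ± 1.15 log2 (adjusted p = 3.18e-06). Upk3a, a uroplakin gene, fell from 613 ± 222 to 0.381 ± 0.329 CPM (-10.58 ± 1.45 log2, adjusted p = 2.94e-06). The potassium channel gene Kcnh1 changed by -8.97 ± 1.02. Among genes of the hormone-sensing state, Esr1 changed by -4.82 ± 0.39 log2 (adjusted p = 1.73e-09), the coactivator gene Cited1 by -5.16 ± 0.55, the pioneer factor gene Foxa1 by -3.53 ± 0.47, the prolactin receptor gene Prlr by -3.65 ± 0.37 and the Wnt ligand gene Wnt4 by -4.29 ± 0.62. Greb1, a classical estrogen receptor target (ENSMUSG00000036523, chromosome 12, 16670615 to 16800886), rose from 1.39 ± 0.73 to 8.87 ± 6.03 CPM (2.68 ± 0.54 log2, adjusted p = 3.3e-04). Myc rose by 1.68 ± 0.31 log2. Elf5, the alveolar transcription factor gene, rose by 2.50 ± 0.46. Mfge8, a milk fat globule gene, rose from 1125 ± 177 to 7129 ± 2750 CPM. The milk protein gene Csn1s2b had 3 counts over the WT placebo libraries and 166 over the WT E2 libraries, a CPM ratio of 50.8 with a counting interval of 17.1 to 249. Of 18426 genes, 2873 were higher and 2923 lower. Of the called genes, 3380 changed by 2-fold or more. Pgr, the progesterone receptor gene, was called lower (-1.46 ± 0.37 log2, adjusted p = 0.00326). Without WT placebo 1 the value was -0.95 with an adjusted p of 0.0645. Tnfsf11 (RANKL) was called higher by 5.10 ± 1.34 log2. Without WT E2 1 the value was -0.33 with an adjusted p of 0.911.

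In the gene lists, luminal progenitor and alveolar markers had 16 higher and 0 lower of 18 (17 and 0 adjusted over the list alone, adjusted p = 1.09e-10, 0.276 with an estimated correlation) in WT E2. The hormone-sensing luminal genes had 1 higher and 14 lower of 19 (2 and 14 over the list alone, adjusted p = 1.12e-06, 0.276 with an estimated correlation). For the type I interferon response the counts were 15 higher and 0 lower of 24 (16 and 0 over the list alone, adjusted p = 2.96e-06, 0.276 with an estimated correlation). Ifit3 was at 0.343 ± 0.064 CPM in placebo and 21.8 ± 16 in E2. Milk protein and lipid secretion genes had 7 higher and 0 lower of 16 (9 and 0 over the list alone, adjusted p = 6.82e-04, 0.276 with an estimated correlation). Keratins and mucins had 7 higher and 1 lower of 15 (8 and 1 over the list alone, adjusted p = 0.0115, 0.276 with an estimated correlation). Estrogen receptor targets had 9 higher and 3 lower of 26 (10 and 3 over the list alone, adjusted p = 0.0302, 0.276 with an estimated correlation). The S phase genes had 13 higher and 0 lower of 26 (15 and 0 over the list alone, adjusted p = 7.47e-06, 0.5 with an estimated correlation). G2 and M phase genes had 0 higher and 1 lower of 30 (0 and 0 over the list alone, adjusted p = 1.29e-04, 0.591 with an estimated correlation). Their mean log2 fold change was 0.927. It was 3.479 without WT placebo 2, 0.446 without WT placebo 1, 0.487 without WT placebo 3 and 0.432 without WT E2 1. Immediate early and dissociation stress genes had 2 higher and 12 lower of 20 (2 and 15 over the list alone, adjusted p = 2.96e-05, 0.276 with an estimated correlation). Among them, Nr4a1 changed by -3.61 ± 0.45 log2. Leukocyte markers had 7 higher and 0 lower of 17 (11 and 0 over the list alone, adjusted p = 0.00199, 0.5 with an estimated correlation). Their mean log2 CPM was -2.47, -2.02 and -2.67 in the WT placebo libraries and 1.6, -1.19 and -0.48 in WT E2. The other lists did not pass. These were progesterone receptor and steroid targets (3 higher and 5 lower of 20, adjusted p = 0.174), paracrine factors (5 and 3 of 18, adjusted p = 0.788), basal markers (3 and 2 of 16, adjusted p = 0.983), fibroblast markers (1 and 0 of 12, adjusted p = 0.314), endothelial markers (0 and 1 of 12, adjusted p = 0.513) and adipocyte markers (0 and 0 of 8, adjusted p = 0.983). Erythroid markers (2 and 0 of 5, adjusted p = 0.137), the unfolded protein response (7 and 3 of 22, adjusted p = 0.174) and cholesterol biosynthesis (2 and 2 of 23, adjusted p = 0.983) were also not called. Glycolysis (6 and 2 of 15, adjusted p = 0.137), MHC class II genes (4 and 2 of 6, adjusted p = 0.155) and mitochondrially encoded genes (0 and 0 of 12, adjusted p = 0.513) completed them. The call of the estrogen receptor targets was lost without WT placebo 3 (adjusted p = 0.0567) and without WT E2 3 (adjusted p = 0.0949), within 0.0132 to 0.0949 over the alternatives. That of keratins and mucins was lost in 3 of 9 alternatives (adjusted p 0.00329 to 0.0949), among them without WT placebo 2 (0.0599) and without WT E2 3 (0.0949).

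**Figure D3:**
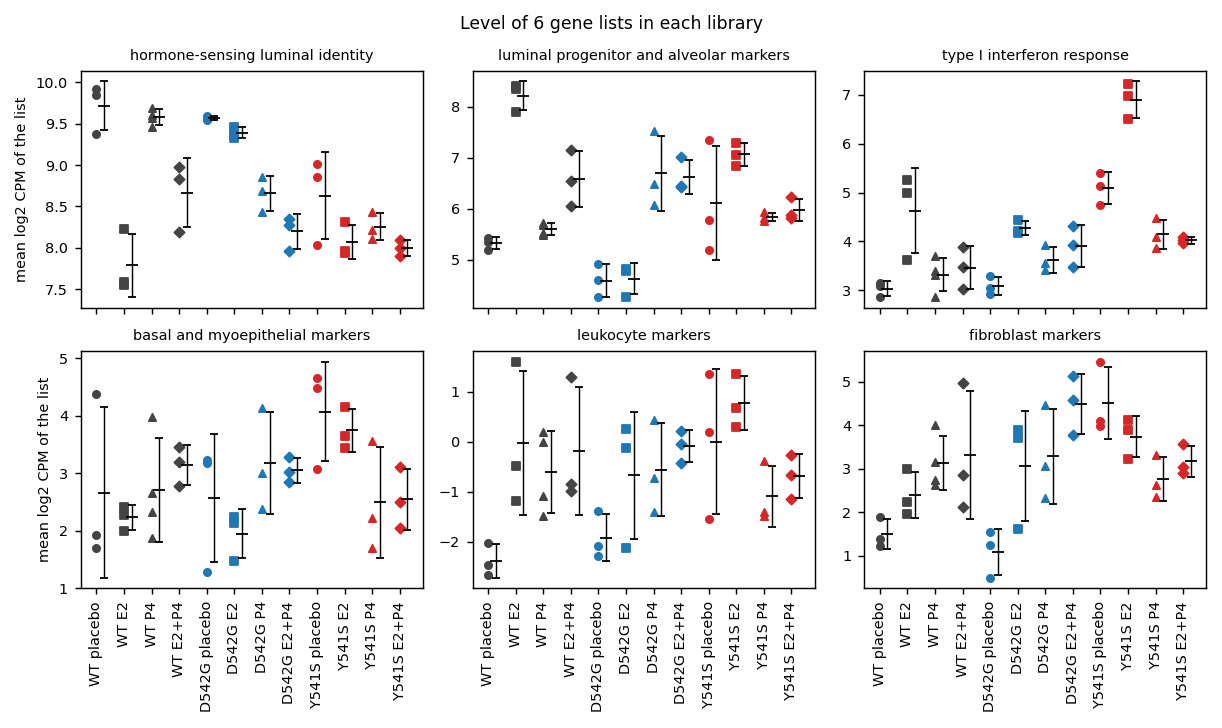
Mean log2 CPM per library of hormone-sensing, progenitor and alveolar, interferon, basal, leukocyte and fibroblast lists, by group; each point is a library. Progenitor and alveolar markers were at 5.33 ± 0.12 in WT placebo and 8.22 ± 0.28 in WT E2 (mean ± SD).

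WT P4 against WT placebo asked what progesterone changes alone. Calca, which encodes calcitonin and CGRP (ENSMUSG00000030669, chromosome 7, 114631478 to 114636357), was at 14.1 ± 6.47 CPM in placebo and 282 ± 266 in P4 (n = 4; 4.32 ± 0.89 log2, adjusted p = 0.014). Tph1, the rate-limiting enzyme of serotonin synthesis, was called higher by 3.35 ± 0.67 log2 (adjusted p = 0.0101). Bmp3, a bone morphogenetic protein gene, was higher by 3.22 ± 0.60 (adjusted p = 0.00608). Among paracrine genes, Tnfsf11 (ENSMUSG00000022015, chromosome 14, 78277445 to 78308043) went from 0.231 ± 0.111 to 16.2 ± 16.8 CPM (6.12 ± 1.34 log2, adjusted p = 0.0198). Areg, an EGF receptor ligand gene, went from 105 ± 25.4 to 488 ± 290 (2.22 ± 0.47 log2, adjusted p = 0.0154). Esr1 (-0.36 ± 0.31 log2, adjusted p = 0.678), Pgr (-1.02 ± 0.34, adjusted p = 0.137) and Greb1 (1.61 ± 0.51, adjusted p = 0.112) were not called. In all, 170 genes were higher and 93 lower, 123 of them by 2-fold or more, and 2556 genes had an unadjusted p under 0.05. Paracrine factors had 4 higher and 0 lower of 18 (5 and 0 over the list alone, adjusted p = 0.00369, 0.0247 with an estimated correlation). No other list kept its call with the estimate. Progesterone receptor and steroid targets had 3 higher and 0 lower of 20 (5 and 0 over the list alone, adjusted p = 0.00775, 0.243 with an estimated correlation), a call lost with the sample number as a block (mean 0.832, adjusted p = 0.0645; 0.00542 to 0.0645 over 10 alternatives). Leukocyte markers had 1 higher and 0 lower of 17 (8 and 0 over the list alone, adjusted p = 7.74e-05, 0.33 with an estimated correlation). Their mean log2 CPM was -0.6 ± 0.82 in WT P4 and -2.39 ± 0.33 in WT placebo. Fibroblast markers had 0 higher and 0 lower of 12 (4 and 0 over the list alone, adjusted p = 0.00232, 0.33 with an estimated correlation). Endothelial markers had 0 higher and 0 lower of 12 (2 and 0 over the list alone, adjusted p = 0.00369, 0.604 with an estimated correlation), at 2.7 ± 1.1 in WT P4 and 1.6 ± 0.12 in WT placebo. Their mean log2 fold change of 1.424 was 0.128 with the block (adjusted p = 0.867) and 0.164 within the first identifier series (0.722), and these 2 of 10 alternatives lost the call. Leaving out single libraries changed the number of calls to 22 without WT placebo 1, 161 without WT placebo 2, 53 without WT placebo 3, 76 without WT P4 3, 139 without WT P4 4 and 116 without WT P4 5. Of 7 such tests, 3 lost the call of Calca (adjusted p = 0.103 without WT placebo 1, 0.106 without WT placebo 3 and 0.0502 without WT P4 3). Tph1 lost its call without WT placebo 1 (0.0828), WT placebo 2 (0.0501) or WT placebo 3 (0.0705). Tnfsf11 lost it without WT placebo 1 (0.134), WT placebo 2 (0.0641), WT placebo 3 (0.107) or WT P4 3 (0.0618). Areg lost it without WT placebo 1 (0.0828), WT placebo 2 (0.0546), WT placebo 3 (0.109) or WT P4 3 (0.0584). Within the first identifier series 228 genes were called, and 79 with the block.

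WT E2+P4 was compared with WT placebo and with WT P4, the latter to ask what E2 adds to P4. Klk1, a kallikrein gene of a multigene family, rose from 0.0443 ± 0.0397 CPM in placebo to 318 ± 175 (12.71 ± 1.93 log2, adjusted p = 1.32e-05). Sftpd, which encodes surfactant protein D, rose from 0.145 ± 0.117 to 339 ± 63.7 CPM (11.19 ± 0.78 log2, adjusted p = 4.56e-11). Greb1 was at 192 ± 64.5 CPM, higher by 7.11 ± 0.64 log2 than in placebo (adjusted p = 3.14e-09) and by 5.50 ± 0.52 than in WT P4 (adjusted p = 6.32e-09). Tnfsf11 rose to 55.5 ± 55.2 CPM (7.90 ± 1.41 log2, adjusted p = 1.15e-04), and the steroid-responsive gene Fkbp5 rose by 5.22 ± 0.56. Upk3a fell to 0.719 ± 0.193 CPM (-9.74 ± 1.40 log2), and Esr1 (-1.55 ± 0.34 log2, adjusted p = 0.00114), Foxa1 (-2.56 ± 0.45) and Cited1 (-1.97 ± 0.48) fell as well. Calca was called higher by 3.26 ± 0.86 log2. Without WT E2+P4 1 the value was 1.11 with an adjusted p of 0.319. Against placebo 2183 genes were higher and 2126 lower (2522 by 2-fold or more), and against WT P4 2220 were higher and 2054 lower (2185 by 2-fold or more). Against WT P4, Esr1 was called lower (-1.19 ± 0.32 log2, adjusted p = 0.00714, but 0.0687 without WT E2+P4 1). Within the first identifier series 2792 genes were called against WT P4. The unfolded protein response had 14 higher and 0 lower of 22 (15 and 0 over the list alone, adjusted p = 1.65e-08, 0.104 with an estimated correlation) against placebo. Edem1, a gene of this list, rose by 2.63 ± 0.22 log2. The estrogen receptor targets had 9 higher and 2 lower of 26 (10 and 2 over the list alone, adjusted p = 7.36e-04, 0.0583 with an estimated correlation) against placebo and 9 higher and 1 lower of 26 (11 and 1 over the list alone, adjusted p = 4.26e-04, 0.0572 with an estimated correlation) against WT P4. Hormone-sensing genes had 1 higher and 10 lower of 19 (1 and 10 over the list alone, adjusted p = 9.93e-04, 0.351 with an estimated correlation). Milk genes had 8 higher and 1 lower of 16 (10 and 1 over the list alone, adjusted p = 9.93e-04, 0.263 with an estimated correlation) against placebo. Leukocyte markers had 7 higher and 0 lower of 17 (8 and 0 over the list alone, adjusted p = 0.00253, 0.383 with an estimated correlation). Their mean log2 CPM was -0.18 ± 1.28 in WT E2+P4. Fibroblast markers were called higher against placebo (3 higher and 0 lower of 12, mean 2.28, adjusted p = 0.0259, 0.4 with an estimated correlation), but not without WT E2+P4 2 (0.831, adjusted p = 0.345).

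The E2+P4 response in WT cells was also set against the sum of the single responses. Esr1 was above the sum by 3.64 ± 0.46 log2 (adjusted p = 5.36e-06), Pgr by 2.84 ± 0.50 (adjusted p = 3.97e-04), Prlr by 2.68 ± 0.46 and Cited1 by 3.20 ± 0.65. Ifit3, an interferon-induced gene, was below the sum (-4.77 ± 0.92 log2, adjusted p = 8.53e-04), and so was Mfge8 (-2.07 ± 0.41). In all, 1178 genes were above the sum and 921 below it. Without WT E2+P4 3, 1229 were called. Interferon genes had 1 higher and 12 lower of 24 (1 and 14 over the list alone, adjusted p = 1.96e-06, 0.581 with an estimated correlation). Progenitor and alveolar markers had 0 higher and 5 lower of 18 (0 and 13 over the list alone, adjusted p = 1.96e-06, 0.581 with an estimated correlation). Leukocyte markers were called lower too (0 higher and 3 lower of 17, mean -2.982, adjusted p = 0.014, 0.891 with an estimated correlation), but not without WT E2 1 (-0.859, adjusted p = 0.269) or WT E2+P4 1 (-2.659, 0.0949). Within the first identifier series 1857 genes were called, and 1331 with the sample number as a block.

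D542G placebo against WT placebo asked what this mutation changes without added hormone. Ctsj, a cathepsin of a multigene family expressed in placenta (ENSMUSG00000055298, chromosome 13, 61000179 to 61005959), was at 0.0732 ± 0.0863 CPM in WT and 218 ± 40.3 in D542G (11.52 ± 1.61 log2, adjusted p = 1.19e-04). Its relative Ctsr was higher by 9.81 ± 1.53. The glucose transporter gene Slc2a3 went from 0.793 ± 0.844 to 220 ± 192 CPM (8.09 ± 1.09 log2, adjusted p = 6.85e-05). Pparg, a nuclear receptor gene, went from 57.1 ± 20.1 to 3.47 ± 0.679 CPM (-4.04 ± 0.74 log2, adjusted p = 0.00175). Greb1 (-0.69 ± 0.55 log2, adjusted p = 0.72) and Pgr (0.50 ± 0.36, adjusted p = 0.676) were not called. In all, 228 genes were higher and 144 lower, 291 by 2-fold or more. Of the lists, MHC class II genes had 1 higher and 0 lower of 6 (2 and 0 over the list alone, adjusted p = 0.00229, 0.546 with an estimated correlation). Glycolysis had 1 higher and 0 lower of 15 (2 and 0 over the list alone, adjusted p = 0.00229, 0.811 with an estimated correlation). The progenitor and alveolar list was called lower with 0 higher and 0 lower of 18 (mean -0.746, adjusted p = 0.00229, 0.811 with an estimated correlation), and passed in 9 other alternatives (mean -0.908 to -0.66, adjusted p up to 0.044). The stress list was called lower with 0 higher and 1 lower of 20 (mean -0.449, adjusted p = 0.00229, 0.811 with an estimated correlation), and passed in those 9 as well (adjusted p up to 0.0199). The MHC class II gene H2-Ab1 was higher by 2.65 ± 0.49 log2. Cited1 was called lower (-2.28 ± 0.49 log2, adjusted p = 0.00866). The call was lost without WT placebo 3 (0.0721), D542G placebo 2 (0.0654) or D542G placebo 3 (0.0835). The number of calls was 189 without WT placebo 1, 178 without WT placebo 2, 206 without WT placebo 3, 196 without D542G placebo 2 and 168 without D542G placebo 3. The glycolysis call was lost without D542G placebo 3 (adjusted p = 0.096).

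The same question was asked of Y541S placebo against WT placebo. Penk was at 0.614 ± 0.16 CPM in WT and 870 ± 380 in Y541S (10.47 ± 1.32 log2, adjusted p = 2.42e-06). Slc2a3 was at 0.793 ± 0.844 and 750 ± 190 (9.87 ± 1.16 log2, adjusted p = 8.28e-07). Cxcl5 was higher by 9.15 ± 1.18 log2. Greb1 was higher by 4.39 ± 0.57 log2 (adjusted p = 3.87e-06), at 29.1 ± 14.2 CPM, whereas Pgr was not called (0.41 ± 0.36, adjusted p = 0.514). Cited1 (ENSMUSG00000051159, chromosome X, 102247381 to 102252181) was lower (-4.77 ± 0.54 log2, adjusted p = 5.56e-07), as were Kcnh1 (-6.22 ± 0.88), Wnt4 (-2.37 ± 0.57) and Foxa1 (-1.81 ± 0.44). Ifit3 was at 26.4 ± 10.9 CPM, higher by 6.25 ± 0.76 log2. Slc16a3, a lactate transporter gene, was higher by 5.18 ± 0.61. The leukocyte gene Ptprc had 3 counts over WT placebo and 273 over Y541S placebo, a CPM ratio of 96.0 (counting interval 32.5 to 468). In all, 1323 genes were higher and 1146 lower, 1450 by 2-fold or more. The number was 1523 without WT placebo 1 and 1487 without WT placebo 3. Estrogen receptor targets had 6 higher and 1 lower of 26 (mean 1.089, adjusted p = 0.00707, 0.2 with an estimated correlation). Interferon genes had 15 higher and 0 lower of 24 (16 and 0 over the list alone, adjusted p = 8.83e-12, 0.2 with an estimated correlation). Hormone-sensing genes had 2 higher and 8 lower of 19 (2 and 8 over the list alone, adjusted p = 1.63e-04, 0.324 with an estimated correlation). Glycolysis had 7 higher and 2 lower of 15 (10 and 2 over the list alone, adjusted p = 1.87e-04, 0.324 with an estimated correlation). Fibroblast markers had 5 higher and 0 lower of 12 (9 and 0 over the list alone, adjusted p = 4.91e-05, 0.206 with an estimated correlation). Leukocyte markers had 4 higher and 0 lower of 17 (8 and 0 over the list alone, adjusted p = 1.19e-04, 0.324 with an estimated correlation). Basal markers had 4 higher and 0 lower of 16 (4 and 0 over the list alone, adjusted p = 0.00707, 0.33 with an estimated correlation). Their mean of 0.747 was 2.591 without WT placebo 2, 0.448 without WT placebo 1, 0.357 without Y541S placebo 3 and 0.492 without Y541S placebo 5, called in each. The progenitor and alveolar list had 6 higher and 0 lower of 18 (7 and 0 over the list alone, adjusted p = 0.0135, 0.468 with an estimated correlation). This call was lost in 5 of 9 alternatives (adjusted p 1.45e-04 to 0.937). Their mean difference was 0.14 without Y541S placebo 5 (adjusted p = 0.707) and 1.08 without WT placebo 2 (adjusted p = 0.053). Within the first identifier series 1786 genes were called.

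The mutants were compared with each other under placebo. Calcb, a calcitonin-related gene, was higher in Y541S by 8.24 ± 1.26 log2 (adjusted p = 7.95e-05), Penk by 8.09 ± 1.18 and the lysophospholipase gene Enpp2 by 7.54 ± 1.14. Greb1 was higher by 5.08 ± 0.59 log2 (adjusted p = 2.81e-06), and Ccn5, a secreted matricellular gene induced by estrogen, by 5.22 ± 0.63. Ache, which encodes acetylcholinesterase, was lower (-5.28 ± 1.14 log2, adjusted p = 0.00284), as was Cited1 (-2.50 ± 0.49). In all, 1218 genes were higher in Y541S and 966 lower, 1283 by 2-fold or more. Estrogen receptor targets had 9 higher and 0 lower of 26 (13 and 2 over the list alone, adjusted p = 9.12e-05, 0.0333 with an estimated correlation). No other list kept its call with the estimate. Interferon genes had 18 higher and 0 lower of 24 (18 and 0 over the list alone, adjusted p = 1.41e-13, 0.0831 with an estimated correlation). Fibroblast markers had 7 higher and 0 lower of 12 (12 and 0 over the list alone, adjusted p = 8.24e-07, 0.0831 with an estimated correlation). Progenitor and alveolar markers had 9 higher and 0 lower of 18 (14 and 0 over the list alone, adjusted p = 9.43e-07, 0.223 with an estimated correlation). Leukocyte (mean 3.041, adjusted p = 8.02e-04), basal (1.4, 3.84e-04) and endothelial markers (1.761, 0.00998) were called higher too. The first 2 calls passed in 9 other alternatives (2.129 to 3.583 and 1.005 to 1.739), and the endothelial call was lost in 4, among them without Y541S placebo 5 (1.004, 0.123). Calls numbered 806 without Y541S placebo 5, 1226 without D542G placebo 1, 979 without D542G placebo 2 and 1396 without D542G placebo 3. They numbered 765 within the first identifier series and 1126 with the block.

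How far the mutants under placebo moved along the E2 response was asked with the 2220 genes higher and 2054 genes lower in WT E2+P4 against WT P4, 2 groups that share no library with the placebo groups. In Y541S placebo the higher genes averaged 0.69 log2 above WT placebo, with 70.5% above 0 (adjusted p = 2.18e-10, 0.0133 with an estimated correlation). Of them 522 were called higher and 70 lower. The lower genes averaged -0.54 (adjusted p = 3.49e-20, 7.16e-04 with an estimated correlation), with 47 called higher and 507 lower. In D542G placebo the higher genes averaged 0.18 log2, with 63.3% above 0 (adjusted p = 2.66e-07, 0.0333 with an estimated correlation). Of them 109 were called higher and 10 lower. The lower genes averaged -0.21 (adjusted p = 2.61e-04, 0.0988 with an estimated correlation), with 15 called higher and 77 lower. Chance overlap of independent calls would have been 159.4 higher and 127.7 lower genes for Y541S, and 27.5 and 16.1 for D542G. Across genes, which are not independent replicates, fold changes of Y541S placebo and WT E2, both against WT placebo, had a Pearson r of 0.574, and D542G placebo had 0.248. Unchanged groups sharing the same controls gave a mean r of 0.5 (SD 0.013) and 0.508 (SD 0.009) in 20 simulations. Within the first identifier series r was 0.454 for Y541S (simulated 0.438, SD 0.01), and without WT placebo 2 and Y541S placebo 5 it was 0.538 (simulated 0.563, SD 0.011), so r did not lie on 1 side of that of the shared control. The covariance for Y541S was 1.705 against a simulated 0.33, and in those settings 1.404 against 0.369 and 2.019 against 0.57. For D542G it was 0.542 against 0.329, 0.618 against 0.371 and 1.086 against 0.582. Over the 10330 genes with an average log2 CPM of at least 2, r was 0.679 for Y541S (simulated 0.498) and 0.074 for D542G (0.499). The covariance there was 0.654 against a simulated 0.062 for Y541S and 0.044 against 0.062 for D542G, so the excess of D542G was not seen at those levels. With WT E2+P4 against WT P4, which shares no library, r was 0.29 for Y541S and 0.137 for D542G (0.503 and 0.243 at those levels). Without WT placebo 2 and Y541S placebo 5 r was 0.113 and -0.007. These controls were not independent: WT placebo 2 and WT P4 2 had r = 0.56 after centring.

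**Figure D4:**
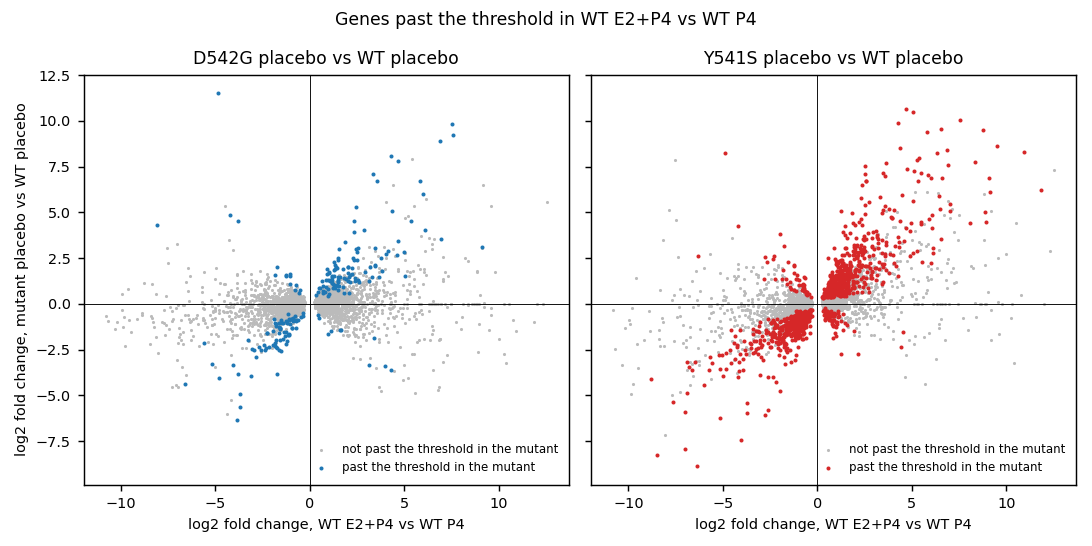
Log2 fold change of each mutant under placebo against WT placebo (y) against that of WT E2+P4 against WT P4 (x), for the genes past the threshold in x; each point is a gene, coloured where it passed in the mutant too. In Y541S 522 genes were higher in both and 507 lower in both.

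D542G E2 against D542G placebo asked how this mutant responds to estrogen. Slpi rose from 3.47 ± 0.663 to 2989 ± 837 CPM (9.75 ± 1.04 log2, adjusted p = 2.58e-07), and Cxcl5 rose by 8.67 ± 1.11 log2. Penk rose from 3.19 ± 3.07 to 1130 ± 357 CPM (8.47 ± 1.19 log2, adjusted p = 1.1e-05). Greb1 rose by 3.04 ± 0.55 log2 (adjusted p = 2.81e-04). Kcnh1 (-6.17 ± 0.92 log2) and Wnt4 (-3.68 ± 0.60) fell. Cited1 (-0.84 ± 0.47, adjusted p = 0.235) and Foxa1 (-0.74 ± 0.43, adjusted p = 0.247) were not called. In all, 1541 genes were higher and 1352 lower, 1610 by 2-fold or more. The number was 1861 without D542G placebo 1 and 1817 without D542G placebo 2. Glycolysis had 10 higher and 0 lower of 15 (12 and 0 over the list alone, adjusted p = 4.37e-10, 0.126 with an estimated correlation). Slc16a3 rose by 4.65 ± 0.58 log2. Estrogen receptor targets had 8 higher and 0 lower of 26 (8 and 0 over the list alone, adjusted p = 6.11e-04, 0.0759 with an estimated correlation). Fibroblast markers had 4 higher and 0 lower of 12 (9 and 0 over the list alone, adjusted p = 0.0044, 0.365 with an estimated correlation), at a mean log2 CPM of 1.09 in placebo and 3.07 in E2. Their call passed in 9 other alternatives (mean 1.757 to 2.775). Endothelial markers, at 1.22 and 3, had 2 higher and 0 lower of 12 (11 and 0 over the list alone, adjusted p = 0.0044, 0.484 with an estimated correlation). Without D542G E2 3 their mean went from 2.075 to 0.781 (adjusted p = 0.144). Leukocyte markers had 3 higher and 0 lower of 17 (adjusted p = 0.0396, 0.62 with an estimated correlation), a call lost without D542G placebo 1 (0.0576), D542G placebo 2 (0.0719), D542G E2 1 (0.119) or D542G E2 3 (0.218). Their mean of 2.117 was 0.995 without D542G E2 1 and 1.138 without D542G E2 3. The hormone-sensing list (4 higher and 5 lower of 19, adjusted p = 0.954) and the progenitor and alveolar list (1 and 1 of 18, adjusted p = 0.954) did not pass. As an interaction, the E2 response in D542G minus that in WT was 7.49 ± 1.57 for Upk3a, 6.05 ± 1.13 for the adrenergic receptor gene Adra2a, 4.32 ± 0.69 for Cited1 and 3.86 ± 0.49 for Esr1 (adjusted p = 1.8e-05). It was -5.34 ± 1.02 log2 for Btbd11 and -2.38 ± 0.42 for Mfge8 (adjusted p = 4.92e-04), and Greb1 was not called (0.35 ± 0.74, adjusted p = 0.85). The interaction was positive for 833 genes and negative for 868. Hormone-sensing genes had 9 higher and 0 lower of 19 (15 and 0 over the list alone, adjusted p = 3.65e-10, 0.13 with an estimated correlation). The progenitor and alveolar list had 0 higher and 12 lower of 18 (0 and 15 over the list alone, adjusted p = 2.99e-13, 0.13 with an estimated correlation).

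D542G P4 against D542G placebo asked the same of progesterone. Tnfsf11 rose from 0.134 ± 0.0457 to 907 ± 221 CPM (12.70 ± 1.63 log2, adjusted p = 1.14e-05). Calca rose from 11.2 ± 1.22 to 5704 ± 2420 (8.99 ± 1.12 log2, adjusted p = 8.63e-06). Rspo1, a Wnt agonist gene, rose by 8.45 ± 1.43 log2 and Fkbp5 by 3.75 ± 0.52. The protease gene Tmprss11a changed by -6.48 ± 0.88 log2, the channel gene Trpc6 by -5.66 ± 0.81 and Pgr by -1.54 ± 0.37 (adjusted p = 0.00464). In all, 1748 genes were higher and 1637 lower, 1980 by 2-fold or more. The number was 1723 without D542G P4 2, 1965 without D542G placebo 2 and 2231 without D542G placebo 3. Progenitor and alveolar markers had 12 higher and 0 lower of 18 (13 and 0 over the list alone, adjusted p = 3.12e-08, 0.316 with an estimated correlation). Hormone-sensing genes had 0 higher and 7 lower of 19 (0 and 9 over the list alone, adjusted p = 5.19e-05, 0.387 with an estimated correlation). Endothelial markers had 5 higher and 0 lower of 12 (11 and 0 over the list alone, adjusted p = 2.47e-04, 0.456 with an estimated correlation). Fibroblast markers had 7 higher and 1 lower of 12 (8 and 1 over the list alone, adjusted p = 0.00358, 0.387 with an estimated correlation). Leukocyte markers were called higher (mean 2.088, adjusted p = 0.032, 0.631 with an estimated correlation), but not without D542G P4 2 (0.858, 0.211), D542G placebo 1 (0.0595) or D542G placebo 2 (0.0751). In the interaction, the response minus that in WT was -8.27 ± 1.76 log2 for Ctsj and -2.33 ± 0.37 for the sterol enzyme gene Msmo1 (adjusted p = 0.00128). For Calca it was 4.67 ± 1.13 (adjusted p = 0.021), a call lost without WT placebo 2 (0.0555), D542G placebo 2 (0.0573) or D542G placebo 3 (0.0606). Tnfsf11 was not called (6.58 ± 2.25, adjusted p = 0.103). The interaction was positive for 279 genes and negative for 338. Called genes numbered 229 without D542G P4 2, 244 without D542G placebo 2, 290 without D542G placebo 3, 254 without WT placebo 2, 364 without WT placebo 3 and 380 without WT P4 5, and 522 within the first identifier series. The progenitor and alveolar list had 5 higher and 0 lower of 18 (12 and 0 over the list alone, adjusted p = 6.19e-08, 0.502 with an estimated correlation). Cholesterol biosynthesis had 0 higher and 3 lower of 23 (0 and 8 over the list alone, adjusted p = 1.59e-04, 0.502 with an estimated correlation). Mitochondrially encoded genes were called higher with 0 higher and 0 lower of 12 (mean 1.35, adjusted p = 0.0128, 0.593 with an estimated correlation). Their mean log2 CPM ran from 4.38 to 7.03 in D542G P4, and the call was lost without D542G P4 2 (0.245, adjusted p = 0.597), without D542G placebo 2 (1.193, 0.0602) and within the first identifier series (1.238, 0.0807).

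In D542G E2+P4, Tnfsf11 was at 426 ± 96 CPM (11.61 ± 1.59 log2 against D542G placebo, adjusted p = 4.05e-06). Rspo1 rose by 8.90 ± 1.45. The metalloprotease gene Adam8 rose by 8.46 ± 0.84 log2. Greb1 rose to 67.3 ± 15.3 CPM (6.28 ± 0.62 log2, adjusted p = 3.47e-08). Ctsj fell to 0.067 ± 0.0199 CPM (-11.60 ± 1.60 log2, adjusted p = 4.71e-06), and the mucin gene Muc16 fell too (-9.80 ± 1.29). In all, 2392 genes were higher and 2293 lower, 2729 by 2-fold or more. Hormone-sensing genes had 0 higher and 14 lower of 19 (0 and 15 over the list alone, adjusted p = 6.52e-08, 0.166 with an estimated correlation). The S phase genes had 14 higher and 0 lower of 26 (18 and 0 over the list alone, adjusted p = 8.15e-07, 0.482 with an estimated correlation). Estrogen receptor targets had 10 higher and 3 lower of 26 (10 and 4 over the list alone, adjusted p = 0.00158, 0.148 with an estimated correlation). Fibroblast markers had 8 higher and 0 lower of 12 (9 and 1 over the list alone, adjusted p = 2.2e-04, 0.199 with an estimated correlation). Leukocyte (mean 2.261, adjusted p = 0.016, 0.576 with an estimated correlation) and endothelial markers (1.884, 0.00277, 0.546) were called higher too, and in 9 other alternatives (1.832 to 2.803 and 1.583 to 2.252). In the interaction with WT cells the early response gene Egr1 was at 2.49 ± 0.53 log2 (adjusted p = 0.0064) and Sftpd at -4.27 ± 0.87. Greb1 was not called (-0.83 ± 0.74, adjusted p = 0.62). The interaction was positive for 214 genes and negative for 578. The number of calls was 382 without WT E2+P4 3, 438 without WT E2+P4 2, 1271 without WT E2+P4 1, 412 without WT placebo 2, 504 without D542G placebo 2, 472 without D542G placebo 3 and 473 without D542G E2+P4 3. Stress genes had 2 higher and 0 lower of 20 (7 and 1 over the list alone, adjusted p = 0.00279, 0.725 with an estimated correlation). This call was lost without WT E2+P4 1 (adjusted p = 0.0777).

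Y541S E2 against Y541S placebo asked whether this mutant still responds to estrogen. The milk protein genes Csn1s2a (5.20 ± 1.53 log2, adjusted p = 0.0465) and Lalba (3.82 ± 0.90, adjusted p = 0.0114) were called higher. Csn1s2a lost its call without Y541S placebo 2 (0.179), Y541S placebo 3 (0.174), Y541S E2 1 (0.268), Y541S E2 2 (0.0622) or Y541S E2 3 (0.0585), and its value was 9.68 without Y541S placebo 5. Lalba lost its call without Y541S placebo 2 (0.0837), Y541S placebo 3 (0.0883) or Y541S E2 1 (0.116). Spdef, an ETS factor gene of secretory epithelium, fell from 26.9 ± 18.1 to 2.32 ± 1.32 CPM (-3.54 ± 0.45 log2, adjusted p = 5.81e-05). The synapsin gene Syn2 changed by -4.22 ± 0.75. Cited1 rose from 45.9 ± 15.3 to 280 ± 106 CPM (2.61 ± 0.49 log2, adjusted p = 0.00198). Among interferon genes, Cmpk2 rose by 2.61 ± 0.29 log2, and Irf7 by 2.35 ± 0.42. Ifit3 was at 26.4 ± 10.9 and 170 ± 42 CPM. Greb1 (-0.27 ± 0.49 log2, adjusted p = 0.835), Esr1 (-0.30 ± 0.33, adjusted p = 0.707) and Pgr (-0.42 ± 0.36, adjusted p = 0.613) were not called. In all, 344 genes were higher and 513 lower, 496 by 2-fold or more. Calls numbered 1786 without Y541S placebo 5, 377 without Y541S placebo 2, 300 without Y541S placebo 3, 299 without Y541S E2 1 and 357 without Y541S E2 3, and 1743 within the first identifier series. Interferon genes had 16 higher and 0 lower of 24 (20 and 0 over the list alone, adjusted p = 2.52e-23, 0.0304 with an estimated correlation). Milk genes had 3 higher and 0 lower of 16 (6 and 0 over the list alone, adjusted p = 3.72e-08, 0.0409 with an estimated correlation). Hormone-sensing genes were called lower (1 higher and 5 lower of 19, mean -0.653, adjusted p = 2.03e-04, 0.699 with an estimated correlation), and in 9 other alternatives (-0.836 to -0.459). The progenitor and alveolar list was called higher (2 and 0 of 18, mean 0.62, adjusted p = 1.69e-04, 0.699 with an estimated correlation). Its mean was 0.285 without Y541S placebo 3 (adjusted p = 0.0522), 0.412 without Y541S placebo 2 and 1.556 without Y541S placebo 5. Leukocyte markers did not pass (0 higher and 0 lower of 17, adjusted p = 0.211). As an interaction, the response minus that in WT was 7.77 ± 0.74 log2 for Cited1, 7.10 ± 1.57 for Upk3a, 4.53 ± 0.49 for Esr1, -8.99 ± 1.46 for Penk and -7.96 ± 1.28 for Slc2a3. For Greb1 it was -2.95 ± 0.72 (adjusted p = 0.01, but 0.0908 without both WT placebo 2 and Y541S placebo 5). The interaction was positive for 740 genes and negative for 738. Called genes numbered 982 without Y541S placebo 5, 909 without WT placebo 3, 941 without Y541S E2 1 and 941 within the first identifier series. Progenitor and alveolar markers had 0 higher and 9 lower of 18 (0 and 14 over the list alone, adjusted p = 1.16e-07, 0.38 with an estimated correlation). Hormone-sensing genes had 6 higher and 1 lower of 19 (7 and 2 over the list alone, adjusted p = 9.24e-04, 0.501 with an estimated correlation). Fibroblast (0 higher and 1 lower of 12, mean -2.009, adjusted p = 0.0421) and leukocyte markers (0 and 3 of 17, -3.273, 0.0174) were called lower too (adjusted p = 0.538 each with an estimated correlation). Both calls were lost with the block (adjusted p = 0.1 and 0.0906), without Y541S placebo 5 (-1.17 and -2.362, 0.115 or more) and without WT E2 1 (-1.515 and -1.147, 0.139 and 0.217). The fibroblast call was also lost without WT placebo 1 (0.0719) or Y541S E2 1 (0.0826).

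Under P4, Tnfsf11 in Y541S cells rose from 1.54 ± 1.61 to 258 ± 52.1 CPM (7.46 ± 1.28 log2, adjusted p = 3.14e-04). Calca rose from 6.18 ± 5.85 to 457 ± 58.9 (6.19 ± 0.99 log2, adjusted p = 1.36e-04). The adenosine receptor gene Adora1 rose by 5.98 ± 0.57 log2. The cornified envelope gene Ivl (-6.74 ± 1.49 log2), the tryptophan-degrading enzyme gene Ido1 (-6.02 ± 1.13) and the chemokine gene Cxcl12 (-5.07 ± 0.57) fell. In all, 948 genes were higher and 1129 lower, 1101 by 2-fold or more. The number was 1167 without Y541S P4 1, 1287 without Y541S P4 2 and 1172 without Y541S P4 3, and 2162 within the first identifier series. Interferon genes had 0 higher and 9 lower of 24 (0 and 13 over the list alone, adjusted p = 5.48e-06, 0.515 with an estimated correlation). Glycolysis had 0 higher and 5 lower of 15 (0 and 9 over the list alone, adjusted p = 3.42e-04, 0.515 with an estimated correlation). Basal markers had 0 higher and 4 lower of 16 (0 and 4 over the list alone, adjusted p = 8.93e-04, 0.515 with an estimated correlation). Fibroblast (mean -2.101, adjusted p = 0.0181) and endothelial markers (-1.582, adjusted p = 0.0427) were called lower (adjusted p = 0.515 and 0.694 with an estimated correlation), but not with the block (adjusted p = 0.0687 and 0.42) or without Y541S placebo 5 (-1.263 and -0.828, adjusted p = 0.16 and 0.499). The endothelial call was also lost without Y541S placebo 3 (0.0633) or Y541S P4 1 (0.0981). Progesterone receptor and steroid targets did not pass (5 higher and 2 lower of 20, adjusted p = 0.11). In the interaction the response minus that in WT was 4.63 ± 0.73 log2 for Dpysl5, -7.83 ± 0.97 for Tph1 and -5.54 ± 0.72 for Cxcl12 (adjusted p = 4.09e-05). Neither Tnfsf11 (1.34 ± 1.82, adjusted p = 0.73) nor Calca (1.87 ± 1.10, adjusted p = 0.332) was called. The interaction was positive for 637 genes and negative for 713. The number of calls was 692 without Y541S P4 3, 760 without Y541S P4 1, 879 without Y541S P4 2, 897 without WT placebo 2 and 829 without WT placebo 3, 510 within the first identifier series and 349 with the block (307 of them among the 1350). Leukocyte markers had 0 higher and 2 lower of 17 (0 and 9 over the list alone, adjusted p = 1.56e-04, 0.424 with an estimated correlation). Interferon genes had 0 higher and 5 lower of 24 (0 and 11 over the list alone, adjusted p = 6.14e-05, 0.424 with an estimated correlation). Paracrine factors had 0 higher and 3 lower of 18 (1 and 4 over the list alone, adjusted p = 0.00577, 0.0709 with an estimated correlation).

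In Y541S E2+P4, Tnfsf11 was at 206 ± 7.95 CPM (7.14 ± 1.27 log2 against Y541S placebo, adjusted p = 2.34e-04). Calca was at 183 ± 87.8 (4.87 ± 0.93 log2). Foxa1 (-2.42 ± 0.45 log2), Ctsr (-8.39 ± 1.44) and the fibrinogen gene Fgb (-8.00 ± 1.33) fell. Greb1 was not called (0.10 ± 0.49 log2, adjusted p = 0.925), at 29.1 ± 14.2 CPM in placebo and 31.1 ± 4.52 in E2+P4. In all, 1554 genes were higher and 1863 lower, 1747 by 2-fold or more. The number was 2202 without Y541S E2+P4 3 and 3601 within the first identifier series. Stress genes had 0 higher and 11 lower of 20 (1 and 13 over the list alone, adjusted p = 1.89e-06, 0.531 with an estimated correlation). Interferon genes had 0 higher and 10 lower of 24 (0 and 15 over the list alone, adjusted p = 8.76e-06, 0.531 with an estimated correlation). The unfolded protein response had 9 higher and 0 lower of 22 (10 and 0 over the list alone, adjusted p = 0.0028, 0.531 with an estimated correlation). Basal markers went from 4.07 to 2.54 in mean log2 CPM (0 higher and 2 lower of 16, adjusted p = 0.0113, 0.531 with an estimated correlation) and endothelial markers from 2.86 to 1.35 (1 and 2 of 12, adjusted p = 0.0235, 0.547 with an estimated correlation). Both calls were lost with the block (adjusted p = 0.0555 and 0.269) and without Y541S placebo 5 (0.118 and 0.278), and that of the endothelial list without Y541S E2+P4 3 (0.132). Without Y541S placebo 5 the mean log2 fold changes went from -1.759 to -1.502 for the basal list and from -1.717 to -0.96 for the endothelial list. Estrogen receptor targets (4 higher and 5 lower of 26, adjusted p = 0.884) did not pass. As an interaction, the response minus that in WT was 7.48 ± 0.85 log2 for the growth factor gene Ptn, -9.90 ± 0.88 for Sftpd (adjusted p = 2.59e-08) and -7.02 ± 0.77 for Greb1 (adjusted p = 6.02e-07). The interaction was positive for 552 genes and negative for 1047. Calls numbered 1414 within the first identifier series. Estrogen receptor targets had 1 higher and 6 lower of 26 (1 and 9 over the list alone, adjusted p = 2.94e-04, 0.0602 with an estimated correlation). Interferon genes had 0 higher and 11 lower of 24 (1 and 12 over the list alone, adjusted p = 4.89e-05, 0.241 with an estimated correlation). MHC class II genes had 0 higher and 5 lower of 6 (0 and 5 over the list alone, adjusted p = 9.97e-05, 0.0728 with an estimated correlation).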

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

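Tests on Y541S placebo 5, on the marker shift in WT E2 and on the interferon genes in Y541S E2 were chosen after the results had been seen. So was the count without WT placebo 2 and Y541S placebo 5.

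In WT P4, the group of 4 libraries, 1 lay far from the rest in 16 of 91 tests. Genes with up to 3 counts in the group were left out, and the tests were not independent, so no chance rate holds. WT P4 2 had the proliferation gene Mki67 at 37.6 CPM (others 0.672 to 2.39), Cdc20 at 29.3 (3.92 to 6.63), Nusap1 at 10.7 (0.324 to 1.94), the fibroblast gene Dcn at 236 (17.1 to 18) and Myc at 193 (248 to 256). Its mean log2 CPM was 4.06 for S phase genes (others 2.36 to 2.61), 4.23 for G2 and M phase genes (0.63 to 1.15) and 5.36 for cholesterol biosynthesis (4.53 to 4.67). WT P4 3 had the collagen genes Col1a1 at 68.6 CPM (3.17 to 11.7), Col1a2 at 101 (4.71 to 9.35) and Col3a1 at 212 (20.6 to 41), and Tubb4a at 52.3 (26 to 29.3). WT P4 4 had Cited1 at 1590 (1100 to 1180), the endothelial gene Cldn5 at 11.5 (5.41 to 6.17) and Creld2 at 92.9 (74.7 to 76.1). WT P4 5 had Vwf at 98.4 (51.7 to 57.7).

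The responses of the genotypes differed by tests of the difference itself, as log2 differences from the WT response. Under E2, 1701 genes differed in D542G. Upk3a (7.49), Adra2a (6.05), Cited1 (4.32), Esr1 (3.86), Foxa1 (2.78), Prlr (2.62) and Pgr (2.25) differed upward, and Btbd11 (-5.34), Dclk1 (-4.94) and Elf5 (-2.19) downward. The hormone-sensing list averaged 1.71 and the progenitor and alveolar list -2.87. Under P4, 617 genes differed in D542G, with Calca at 4.67, Gabrg3 at 4.45 and Ctsj at -8.27. The progenitor list averaged 1.93 and the hormone-sensing list -0.74. Under E2+P4, 792 genes differed in D542G, with Ier5l at 5.15, Dusp2 at 4.89 and Dpep2, whose span lies wholly within other genes, at -6.69. The stress list averaged 0.78 and glycolysis -0.62. With an estimated correlation no list kept its call in any test of a difference between responses, in either mutant or for the sum of responses in WT cells (lowest adjusted p 0.0602). In D542G it was 0.502 for hormone-sensing genes under P4 and 0.725 for stress genes and glycolysis under E2+P4. The call of Elf5 was lost in 4 of 12 tests that left out a library (adjusted p up to 0.0743, without WT E2 2), that of Gabrg3 in 4 of 13 (0.122, without D542G P4 2), of Ier5l in 6 of 12 (0.0918, without D542G E2+P4 2) and of Dusp2 in 1 of 12 (0.0524, without WT E2+P4 3).

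In Y541S, 1478 genes differed from WT in the E2 response, with Cited1 at 7.77, Upk3a at 7.1, Esr1 at 4.53, Wnt4 at 2.82, Foxa1 at 2.61, Prlr at 1.8, Penk at -8.99, Slc2a3 at -7.96, Greb1 at -2.95, Elf5 at -2.49 and Myc at -1.39. The progenitor list averaged -2.37 and the stress list 1.03 (adjusted p = 0.38 and 0.447 with an estimated correlation). Under P4, 1350 genes differed, with Dpysl5 at 4.63, Ppp1r1b at 4.54 (75.4% of its span overlapped by other genes), Tph1 at -7.83 and Col1a2 at -7.74. The leukocyte list averaged -4.2 and the interferon list -1.41. Under E2+P4, 1599 genes differed, with Ptn at 7.48, Col8a1 at 6.41, Sftpd at -9.9, Dpep2 at -8.76, Greb1 at -7.02 and Elf5 at -2.11. MHC class II genes averaged -3.21 and interferon genes -1.72. In tests that left out a library the E2 difference lost the call of Myc in 7 of 12 (up to 0.294, without Y541S placebo 5), Wnt4 in 5 (0.0897, without Y541S E2 1), Elf5 in 1 (0.0751, without Y541S placebo 5) and Prlr in 1 (0.0519, without WT E2 2). Col1a2 lost it in 4 of 13 (0.0559) and Elf5 under E2+P4 in 6 of 12 (0.16), the highest for both without Y541S placebo 5.

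In WT cells the E2 effect with and without P4 differed for 2099 genes. Kcnip3 (5.8), Prom2 (5.7), Esr1 (3.64), Cited1 (3.2), Pgr (2.84), Greb1 (2.82), Prlr (2.68), Wnt4 (2.59) and Foxa1 (1.77) lay above the sum of the single responses. Htra3 (-5.41), Clca1 (-5.25) and Elf5 (-1.92) lay below it, and so did the averages of the progenitor list (-1.9) and the interferon list (-1.79). In 13 tests that left out a library, Foxa1 lost its call in 9 (up to 0.283), Elf5 in 8 (0.13) and Wnt4 in 3, each highest without WT E2+P4 3, and Greb1 in 1 (0.0527, without WT placebo 1).

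Other splits of the same libraries were set beside the numbers of genes called. Chance is not excluded for WT E2+P4 against WT P4 (1 of 35 splits as large, real 4274, highest other 2595, uncorrected over 20 tests). Nor is it for WT P4 against placebo (2 of 35). The other split gave 267 genes against 263 and set WT P4 4 and 5 with WT placebo 1 and 3, apart from WT P4 2 and 3 and WT placebo 2. It follows the later identifier series in part, and within the first series 228 genes were called. Chance was not excluded for the E2 response in D542G (3 of 25 splits, 1701, highest other 3810), the E2+P4 response in D542G (4 of 25, 792, 2596), the E2 response in Y541S (3 of 25, 1478, 2938) and the E2+P4 response in Y541S (2 of 25, 1599, 1981). In each the split with most calls mixed 1 genotype only and returned the other's own hormone response. Splits within a genotype thus cannot test whether responses differ. The same holds for the P4 responses of both mutants and the sum of responses in WT cells. At 1 of 25 splits each, real values were 617, 1350 and 2099 (highest others 135, 606 and 81). In the others 10 splits are too few for a share under 0.05, with the real split as 1 of 10. Real values and highest others were 5796 and 17 for WT E2, 4309 and 6 for WT E2+P4, 372 and 46 for D542G placebo, 2469 and 27 for Y541S placebo, and 2184 and 5 for Y541S against D542G placebo. They were 2893 and 2 for D542G E2, 3385 and 2 for D542G P4, 4685 and 0 for D542G E2+P4, 857 and 672 for Y541S E2, 2077 and 122 for Y541S P4, and 3417 and 397 for Y541S E2+P4.

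Y541S placebo 5 stood apart from Y541S placebo 2 and 3, and 402 genes differed at least 4-fold, with a median size of 2.46 log2. A difference between the identifier series, depth included, would have shifted the same genes in WT P4 4 and 5, but their median signed shift there was 0.044 (bootstrap SE 0.041), below a bound of 0.61. Over all tested genes the library correlated at 0.419 or more with the Y541S E2 libraries and at 0.086 to 0.17 with Y541S placebo 2 and 3, whose own correlation was 0.415. Of genes at least 4-fold apart between 2 Y541S E2 libraries and Y541S placebo 2 and 3, it lay nearer to E2 in 72% to 82.2%, against 92.7% to 95.9% for a Y541S E2 library left out. Its interferon list was at 5.4 (Y541S E2 6.5 to 7.23), its fibroblast list at 5.46 (3.22 to 4.12) and Cited1 at 30.6 CPM (158 to 351.6). These values argue against a Y541S E2 library like the other 3. Another wrong label cannot be told apart from such a series difference or from a difference between mice, which was not tested. Without it 1786 genes were called in Y541S E2 against placebo, where 857 were called with it.

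Hormone-sensing markers were lower and progenitor and alveolar markers higher in WT E2 than in WT placebo. The shift of the progenitor list mean was 2.89 ± 0.17 (SE) and that of the basal list -0.43 ± 0.87, a gap of 3.32 ± 0.88. Without WT placebo 2 the basal shift was 0.42 ± 0.17 and the gap 2.41 ± 0.24. Fibroblast and endothelial markers, not called in this comparison, had shifts of 0.9 ± 0.37 and 0.57 ± 0.25, with gaps of 1.99 ± 0.41 and 2.32 ± 0.3. These gaps argue against a higher share of all other cell types alike. Leukocyte (2.36 ± 0.86) and erythroid markers (1.83 ± 0.51) lay within 2 SE of the progenitor list (gaps 0.53 ± 0.88 and 1.06 ± 0.54) and do not count against it. Mfge8, the most abundant progenitor list member, was at 1125 ± 177 and 7129 ± 2750 CPM. More progenitor cells would lower hormone-sensing markers that are no estrogen receptor targets by 1 common factor only if progenitors lacked them, which is untested. Their log2 fold changes (SD 1.88, typical SE 0.37) thus cannot decide. Too few of them rose to decide, so more progenitor cells and a response of the luminal cells to E2 cannot be told apart.

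Interferon genes were higher in Y541S E2 than in Y541S placebo, at 0.44% and 0.132% of counts. Leukocytes in the sorted fraction would raise the leukocyte list too. Its share rose by 5.67e-05 percentage points (SE 0.00494), and the interferon list by 0.308. Without Y541S placebo 5, the highest of its group, these were 0.00474 (SE 0.00185) and 0.316, so leukocytes are not excluded. Cd74, highest of the leukocyte list, was at 65.9 ± 39 and 46.6 ± 11.3 CPM. Without each of the 6 libraries in turn the highest adjusted p was 3.36e-16 and the lowest mean log2 fold change 1.62, which argues against a single library. A response of Y541S cells to E2 remains a hypothesis, with other differences between the mice untested.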

How the results depend on the processing

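The removal of WT placebo 2 and Y541S placebo 5 together was chosen after the results had been seen, and the other alternatives were planned. Genes of low count in a group gave ratios with counting intervals only, genes inside other genes were uncertain, and each group had 3 or 4 libraries. With 3 libraries per group, simulated 2-fold changes of genes above a minimum mean CPM were recovered in 34% in the WT E2 design. In the Y541S E2 interaction 10% were recovered.

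Of 1494 gene results named by the rule, 1018 were called, and 706 of these kept their call without each library in turn. DESeq2 gave the same side of the threshold for 1376 results, RLE factors for 1484, no filter on low counts for 1416, the first identifier series for 1319 and the tests without WT placebo 2 and Y541S placebo 5 for 1306. Of 190 list calls, 186 were lost with an estimated correlation. The 4 kept were paracrine factors in WT P4, estrogen receptor targets in Y541S against D542G placebo, and milk and interferon genes in Y541S E2. Of 440 list results, 401 kept their side within the first series and 396 without the 2 libraries. The cause was not tested for any change named here, apart from fewer libraries or other genes tested.

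DESeq2 with its size factors called 761 genes in WT P4, 667 in D542G placebo and 1439 in Y541S E2. For the differences from the WT response it called 1262 genes for D542G P4, 1425 for D542G E2+P4 and 2130 for Y541S P4. With RLE factors all 20 counts stayed within 1.5 times. Without a filter on low counts more genes were tested, and WT P4 had 160 calls.

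Without the 3 libraries of the later series there were 2792 calls in WT E2+P4 against WT P4, 765 in Y541S against D542G placebo, 1743 in Y541S E2, 941 in the Y541S E2 difference and 510 in the Y541S P4 difference. The correlation of fold changes with WT E2 was 0.264 for D542G placebo and 0.454 for Y541S placebo, and with WT E2+P4 against WT P4 it was 0.105 and 0.227. Over genes with an average log2 CPM of at least 2 they were 0.074, 0.679, 0.243 and 0.503 (unchanged groups sharing the control 0.499 and 0.498 for the first 2). Without WT placebo 2 and Y541S placebo 5 they were 0.373, 0.538, -0.007 and 0.113 (0.636 and 0.563), so the latter D542G value changed sign. Calls without those 2 libraries numbered 520 in WT P4, 843 in Y541S against D542G placebo, 1837 in Y541S E2 and 621 in the Y541S P4 difference. Of the E2 response lists, the lower genes in D542G placebo (mean -0.208) lost their call with an estimated correlation. All 4 list results kept their direction and call with a list threshold of 0.01, with the block and within the first series.

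The sample number as a block gave 79 calls in WT P4, 1126 in Y541S against D542G placebo, 349 in the Y541S P4 difference and 1331 in the sum of responses in WT cells. With the block, 1321 of the named gene results and 404 of the list results kept their side. Over all groups the numbers did not pair the samples. After centring on groups, 178 pairs with the same number had a median r of 0.001, and 449 others 0.002. The highest were 0.56 (WT placebo 2 and WT P4 2) and 0.387, so some pairing stays open.

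Without each library in turn, calls ranged from 22 to 384 in WT P4, 168 to 261 in D542G placebo, 1487 to 2422 in Y541S placebo and 806 to 2445 in Y541S against D542G placebo. They ranged from 1817 to 2440 in D542G E2, 1723 to 3295 in D542G P4, 299 to 1786 in Y541S E2, 1167 to 2191 in Y541S P4 and 2202 to 3657 in Y541S E2+P4. For the differences they ranged from 229 to 733 for D542G P4, 382 to 1271 for D542G E2+P4, 909 to 1639 for Y541S E2, 692 to 1552 for Y541S P4 and 1229 to 2394 for the sum in WT cells. The other counts stayed within 1.5 times.

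Some results changed direction. Tnfsf11 in WT E2 ranged from -0.327 (without WT E2 1) to 5.678. The G2 and M phase list in WT P4 averaged -0.085 within the first series (not called), 1.794 without WT placebo 2 and Y541S placebo 5 (adjusted p = 0.0191), and -2.612 to 1.792 without each library, the highest without WT placebo 2. In the D542G E2 difference (gene list G2 and M phase genes, E2 response in D542G minus E2 response in WT) it was -1.751 without those 2 libraries, and -1.751 to 1.471 without each. In the Y541S P4 difference it was -1.151 (without WT placebo 2) to 3.253. Without WT placebo 2 the means of the cell cycle lists also changed sign for G2 and M phase in the D542G P4 difference (-1.091) and S phase in the Y541S P4 (-0.072) and D542G E2+P4 (-0.353) differences. Csn1s1 in Y541S placebo was -0.108 without the 2 libraries. The value of Myc, Y541S P4 vs Y541S placebo, was 0.761 within the first series, 0.76 without the 2 libraries and -0.358 to 0.76 without each library.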

Other observations

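Slc2a3, a glucose transporter gene, was at 220 ± 192 CPM in D542G placebo, 1029 ± 213 in D542G E2, 750 ± 190 in Y541S placebo and 287 ± 192 in Y541S E2, against 0.793 ± 0.844 in WT placebo and 76.4 ± 89.4 in WT E2. Ctsj was at 22.2 ± 27.5 CPM in Y541S placebo, and in D542G cells at 218 ± 40.3 in placebo, 68.3 ± 8.79 in E2 and 25.5 ± 17.2 in P4. Penk was at 638 ± 981 CPM in D542G P4 and 36 ± 22.7 in Y541S P4, against 0.597 ± 0.687 in WT P4 (n = 4).

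Markers of other cell types differed between groups of a sorted fraction. Mean log2 CPM of the fibroblast list was 1.51 in WT placebo, 1.09 in D542G placebo and 4.51 in Y541S placebo, and 4.5 in D542G E2+P4. The basal list was at 2.66 in WT placebo (4.37 in WT placebo 2, 1.7 and 1.92 in the others), 2.56 in D542G placebo and 4.07 in Y541S placebo. The leukocyte list was at -2.39 in WT placebo, -1.92 in D542G placebo and 0 in Y541S placebo.

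WT placebo 2 and WT P4 2, at r = 0.56 after centring, were both high in cell cycle and basal genes. WT placebo 3 and WT P4 3 had 0.174.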
